A study of Mus musculus with 16 samples.

How the data were processed

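RNA was measured by spatial transcriptomics (Visium, which captures polyadenylated RNA on an array of barcoded spots) in spinal cord of adult female C57BL/6J mice of 8 to 9 weeks of age, uninjured or after complete transection at thoracic vertebra 10. Per the labels, 16 libraries were made, 1 for each combination of 4 times (uninjured, 3 h, 24 h and 72 h after transection) and 4 positions (1 mm and 0.5 mm rostral, 0.5 mm and 1 mm caudal of the epicentre). Each library holds 4 consecutive cryosections of 20 µm on 1 capture area, so that 64 sections from 9 mice were sequenced. Replicates 1 to 4 of a time denote rostral 1 mm, rostral 0.5 mm, caudal 0.5 mm and caudal 1 mm, in that order. The sample titles call the control animals uninjured and a treatment label calls them sham, and they are called uninjured here. The labels do not say which mouse gave which library. With 16 libraries from 9 mice some libraries share animals, so not all are independent replicates, and p-values between times are too small. Those for distance and side may err either way.

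The deposited matrices hold raw UMI counts (unique molecular identifiers, 1 per captured molecule) per gene and spot, which the authors made with Space Ranger 1.0.0 on the mm10 build, without normalization. The deposited positions files give an in-tissue flag and array coordinates for each spot, a unit of their own class, and the deposited image scale factors were not used. Of the 16 matrices, 14 held in-tissue spots alone, and the matrices of 24 h replicate 4 and 72 h replicate 4 held all 4992 spots of the capture area, of which 1610 and 1400 lay in tissue and were used. The matrix of 72 h replicate 3 had been exported again with gene symbols in place of identifiers and with renamed barcodes. Of its 32285 gene symbols, 32245 equalled those of the other files row for row and the others differed by an added suffix, so that its rows were joined to theirs in order. Genes are identified by the symbols and Ensembl identifiers of the deposited files. Depth per library was 9065388 to 30238164 UMIs over in-tissue spots.

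UMI counts were summed over the in-tissue spots of each library. Gene tests used the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with TMM normalization, filterByExpr by time group and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05 and 2-sided tests. Times were compared in a fit over all 16 libraries with time and position as additive terms (15978 genes tested). Distance (0.5 mm against 1 mm) and side (caudal against rostral) were compared over the 12 injured libraries with time, side and distance as terms (15606 genes tested). Interaction terms over all 16 libraries tested whether the distance or the side difference depended on injury. After the data had been examined, the distance was also tested within each time in a fit of side, time and time by distance over all 16 libraries. Standard errors of log2 fold changes were obtained as the absolute log2 fold change divided by the square root of the F statistic and are approximate. Levels are given as CPM, the UMI counts of the raw library sums scaled to the in-tissue library size, with the SD over libraries, and fold changes come from the fit. For a gene with no UMI in the uninjured group, the fold is a lower bound against a floor of 3 counts over the group. For a gene with 1 to 3 UMIs there, the ratio of CPM over the group is given with its 95% Clopper-Pearson counting interval. Intervals and floors cover counting error alone.

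Spots were grouped by Leiden clustering (leidenalg 0.10.2 on igraph 0.11.9, resolution 0.5) of a graph of 15 nearest neighbours over 20 principal components of 2000 highly variable genes (scikit-learn 1.9.0, NumPy 2.4.6 and pandas 2.3.3 in Python 3.11.15). Clusters were called gray matter, white matter, meninges and nerve roots or blood-led from fixed marker genes. The exact form of that naming rule was written after the clusters had been seen. A spot holds several cells, and these classes are regions, not cell types. Gray matter and white matter counts were summed per library and fitted in edgeR with library, region and region by time as terms (14920 genes tested, 30 sums from 15 libraries). At least 20 spots per region and library were required, which left out 72 h replicate 3 with 10 white matter spots.

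Before the data were examined, the comparisons, 34 gene lists with 425 genes in all, the rule for named genes and most of the alternatives were fixed. The lists are immediate early genes, heat shock, cytokines and chemokines, neutrophil markers, monocyte and macrophage markers, homeostatic microglia markers, activated phagocyte genes, lymphocyte markers, astrocyte baseline markers, reactive astrocyte genes, IGF axis, myelin and oligodendrocyte genes, oligodendrocyte precursor markers, pan-neuronal genes, transmitter genes, cholinergic motor neuron genes, axon growth and nerve injury genes, endothelial and barrier genes, activated endothelium genes, mural cell markers, fibroblast and matrix genes, ependymal markers, Schwann cell markers, red blood cell genes, skeletal muscle genes, cell cycle genes, interferon response genes, antigen presentation genes, complement genes, cholesterol synthesis genes, hypoxia and glycolysis genes, oxidative stress and metal genes, mitochondrially encoded genes and nuclear-encoded respiratory chain genes. Each list was tested at 3 times with camera (limma 3.58.1, voom, preset correlation 0.01, Benjamini-Hochberg over 102 tests), which compares a list with the other genes. Beside it stand camera with an estimated correlation and fry, which tests whether a list moves one way. Member counts are given as adjusted over all genes tested and as adjusted over the list alone.

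By the rule for named genes, each time against uninjured gave the 8 largest rises and the 5 largest falls among genes past the threshold with a mean of at least 10 CPM and the same sign at all 4 positions. It also gave up to 3 members per list with the largest changes past the threshold, or where none passed the member with the highest level, and always Igfbp2, Gap43 and Gfap. Elsewhere it gave the 5 largest changes per direction at a mean of at least 10 CPM and the same 3 genes. Predicted genes were counted but passed over for naming. Genes named outside the rule are said to be so where they appear.

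The share of spots with an Igfbp2 UMI was computed after thinning each spot to 2000 UMIs, with shallower spots left out. Spearman correlations of Igfbp2 with 8 genes over spots were computed within each library on the same thinned counts. Both were compared between each time and uninjured by 2-sided exact permutation tests over libraries (SciPy 1.17.1, 4 against 4, 70 arrangements), adjusted over 3 and 24 tests.

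The alternatives were the DESeq2 1.42.0 Wald test, RLE size factors, no filter or a filter of 10 CPM in 4 libraries, removal of mitochondrially encoded and haemoglobin genes, thinning to the shallowest library, no position term, the 8 libraries compared alone, all 16 libraries for distance and side, spots under 500 UMIs left out, gray or white matter spots alone, Leiden resolutions of 1 and 0.3, limma-voom with library as a random block, a 2-fold minimum, 1000 or 4000 UMIs per spot or no thinning, and each library left out in turn. The fits without the 0.5 mm libraries of 72 h, or without 72 h, were added after the data had been examined. Pipelines were tested on simulated data in which 200 genes had been changed. With 2-fold changes, 60% to 70% of the changed genes were recovered for 3 h, 24 h and 72 h against uninjured, 73% for distance, 70% for side, 15% and 20% for the injury interactions and 81% to 90% for the regional comparisons. With 4-fold changes, 74% to 100% were recovered in these comparisons. Figures were drawn with matplotlib 3.10.9. Results for some genes are not reported here.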

Results

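Spatial transcriptomes were collected from the spinal cord of adult female C57BL/6J mice, uninjured or at 3 h, 24 h or 72 h after a complete transection at thoracic vertebra 10. The 16 libraries comprised 4 per time, 1 at each of the positions rostral 1 mm (replicate 1), rostral 0.5 mm (replicate 2), caudal 0.5 mm (replicate 3) and caudal 1 mm (replicate 4), each from 4 consecutive sections. The sections came from 9 mice, and which mouse gave which library is not stated. The title of the series names IGFBP2, an insulin-like growth factor binding protein, and a distinct astrocyte subpopulation, so Igfbp2 (ENSMUSG00000039323) was followed in each comparison. In-tissue totals of the uninjured replicates 1 to 4 were 20312236, 19368887, 9065388 and 18973800 UMIs. Those of 3 h were 18280057, 15587379, 11996629 and 15042007 UMIs, and those of 24 h were 23993244, 11571189, 19763162 and 29684279 UMIs. The 72 h libraries held 22993944, 12414561, 12481602 and 30238164 UMIs. Per library, 1080 to 1691 spots lay in tissue, with medians of 6316 to 21375 UMIs per spot. Haemoglobin transcripts took 0.0219 ± 0.0234% of UMIs in uninjured cord, 1.48 ± 0.697% at 3 h, 0.754 ± 0.367% at 24 h and 2.04 ± 3.81% at 72 h (mean ± SD, n = 4 libraries). Replicate 3 of 72 h alone held 7.75%.

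The comparison of 3 h with uninjured cord asks which transcripts changed within hours of transection. Values in the accounts of the times are log2 fold changes ± SE from 4 libraries per time unless a unit is named. Chemokine and cytokine transcripts, whose products recruit and activate leukocytes, were among the largest rises. Cxcl1 (ENSMUSG00000029380), a neutrophil attractant, went from 0.0657 ± 0.0516 to 81.6 ± 14.8 CPM (SD, n = 4), a rise of 10.36 ± 0.72. Rises of 9.51 ± 1.35 for Cxcl2, 8.55 ± 0.98 for Il6 and 8.12 ± 1.08 for Ccl2, a monocyte attractant, were also found. Csf3, which encodes the granulocyte growth factor G-CSF, had 1 UMI in all uninjured libraries and 3201 UMIs at 3 h, a CPM ratio of 3559 (95% counting interval 638 to 140620). Of 16 cytokines and chemokines, 14 rose and 2 did not pass (14 adjusted over the list alone), with a list median of 6.04. That list shifted up against the other genes (camera adjusted p = 1.9e-13), a call lost at adjusted p = 0.286 with an estimated correlation. Immediate early genes, which are transcribed within minutes of stimulation, rose in 17 of 19 cases (18 adjusted over the list alone), with Fosb at 7.04 ± 0.55, Maff at 5.18 ± 0.30 and Fos at 5.02 ± 0.45. Their shift had an adjusted p = 3.1e-30, and adjusted p = 0.116 with an estimated correlation. Some libraries of a time share animals, so these p-values are too small.

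Markers of homeostatic microglia, the resident phagocytes of the cord, fell at 3 h. Tmem119 (ENSMUSG00000054675) went from 29.3 ± 4.43 to 3.52 ± 1.41 CPM (SD, n = 4), a log2 fold change of -3.00 ± 0.27. P2ry12, a receptor for ADP, fell from 30.7 ± 2.47 to 4.97 ± 1.21 CPM, and P2ry13 and Gpr34 had log2 fold changes of -3.56 ± 0.29 and -2.58 ± 0.35. Of 12 homeostatic microglia markers, 11 fell and 1 did not pass (11 adjusted over the list alone), with a median of -2.12 and an adjusted p = 1.3e-20 that became 0.0235 with an estimated correlation. Among 13 activated phagocyte genes, 5 fell and 8 did not pass (6 adjusted over the list alone), among them Cst7 at -2.43 ± 0.46, Trem2 at -1.65 ± 0.19 and Tyrobp at -1.05 ± 0.21. The shift of that list had an adjusted p = 4.6e-05, and adjusted p = 0.385 with an estimated correlation. Complement genes divided, with 6 of 12 lower and 2 higher (9 and 2 adjusted over the list alone). The opsonin subunit gene C1qa stood at -1.47 and the anaphylatoxin receptor gene C5ar1 at 3.27 ± 0.50, and the list shifted down at an adjusted p = 0.0018 (adjusted p = 0.404 with an estimated correlation). The libraries share animals, so p-values are too small.

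Vessel genes also divided at 3 h. Adhesion and remodelling genes of activated endothelium rose in 4 of 11 cases and fell in 1 (5 and 1 adjusted over the list alone), with Selp at 5.77 ± 1.11 and Icam1 at 4.36 ± 0.29, which bind leukocytes to the vessel wall. That list shifted up at an adjusted p = 3.2e-04 (adjusted p = 0.404 with an estimated correlation). Of 14 endothelial and barrier genes, 5 fell and 2 rose (6 and 4 adjusted over the list alone), among them the growth factor receptor genes Kdr at -1.64 ± 0.28 and Tek at -1.60 ± 0.22 and the tight junction gene Cldn5 at -1.19 ± 0.23, and the list as a whole did not shift (adjusted p = 0.363). Haemoglobin transcripts, which red blood cells carry, moved with the injury, and Hbb-bs went from 87.2 ± 91.6 to 7443 ± 3863 CPM (SD, n = 4). Oxidative stress and metal genes rose in 4 of 12 cases (5 adjusted over the list alone), with Hmox1, the haem-degrading enzyme, at 2.52 ± 0.53 and the metallothionein Mt2 at 2.05 ± 0.17 (adjusted p = 9.3e-05 for the list, adjusted p = 0.286 with an estimated correlation). Cholesterol synthesis genes rose in 5 of 17 cases (5 adjusted over the list alone), with the isomerase gene Idi1 at 0.93 ± 0.16 (adjusted p = 2.6e-04 for the list, adjusted p = 0.456 with an estimated correlation). No member of the pan-neuronal list of 15 or the transmitter list of 12 passed in edgeR, whether adjusted over all genes or over the list alone, and none did in DESeq2. Snap25, a synaptic protein gene, stood at 0.11 ± 0.47. P-values are too small because libraries share animals.

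Igfbp2, Gap43 and genes that mark or respond in astrocytes moved little or unevenly at 3 h. Igfbp2 stood at 0.43 ± 0.25 (from 36.6 ± 5.34 in uninjured cord to 46.3 ± 1.87 CPM, SD, n = 4) and did not pass (adjusted p = 0.329), but passed in a fit of the 8 libraries alone (0.47, adjusted p = 0.006). Gfap, the intermediate filament of astrocytes, was at -0.98 ± 0.26 with an adjusted p = 0.0329, and this call ended without uninjured replicate 2 or 3 (adjusted p = 0.168 and 0.165), without 3 h replicates 1 to 4 in turn (0.0706, 0.113, 0.0771 and 0.0899) and without the position term (0.247). Gap43, a growth cone protein gene, was at 0.07 ± 0.11. The transcription factor gene Sox9 rose by 0.99 ± 0.14, as the single member of 13 astrocyte baseline markers to pass (1 adjusted over the list alone, adjusted p = 0.255 for the list). Of 16 reactive astrocyte genes, 5 rose and 1 fell (6 and 2 adjusted over the list alone), with Lcn2 at 4.46 ± 0.74, Emp1 at 3.07 ± 0.52 and Tm4sf1 at 2.60 ± 0.48. That shift had an adjusted p = 0.0119, adjusted p = 0.542 with an estimated correlation, adjusted p = 0.204 by fry, and adjusted p = 0.105 without 3 h replicate 1. In all, 862 genes rose and 815 fell at 3 h of 15978 tested by edgeR at an adjusted p of 0.05, and of these 1677 genes 1664 were called in the same direction by DESeq2. The count was 1053, 944 and 1060 without uninjured replicates 1, 2 and 3, and 1076 and 1096 without 3 h replicates 1 and 2. It was 3162 in a fit of the 8 libraries alone and 3192 without the 0.5 mm libraries of 72 h, a setting chosen after the data had been examined. Libraries share animals, and p-values are too small.

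**Figure D1:**
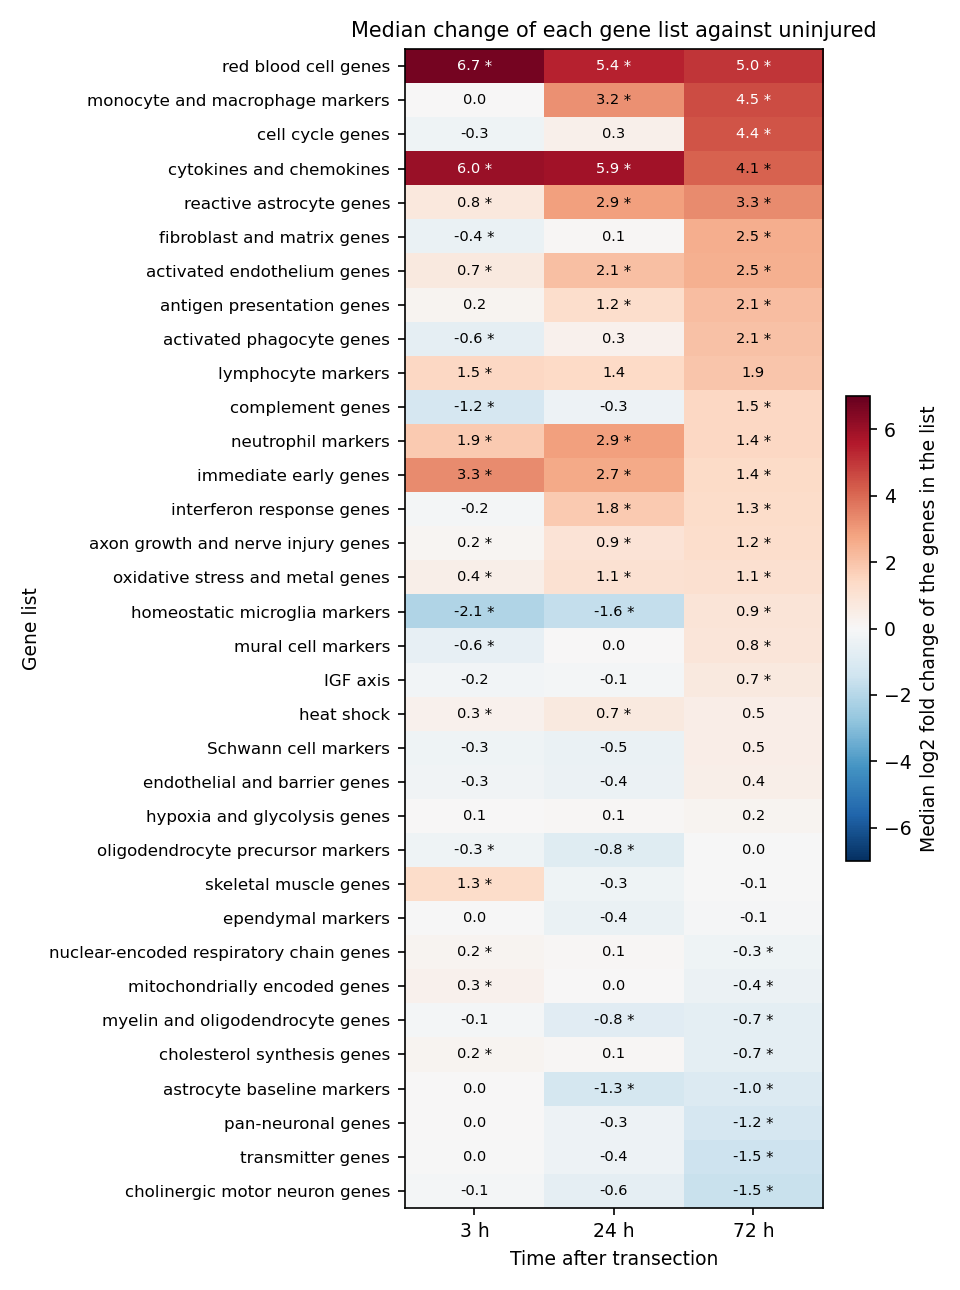
Median log2 fold change of each of 34 gene lists (vertical axis) at 3 h, 24 h and 72 h against uninjured cord (horizontal axis), as colour from -7 to 7, with lists sorted by their 72 h median and stars where the camera adjusted p was under 0.05. Homeostatic microglia markers lie at -2.12 at 3 h and at 0.88 at 72 h, and cell cycle genes reach 4.39 at 72 h.

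The comparison of 24 h with uninjured cord asks which changes were present a day after transection. Arg1 and chemokine transcripts were among the largest rises. Arg1 (ENSMUSG00000019987), the arginase of alternatively activated macrophages, went from 0.251 ± 0.141 to 79.9 ± 54.3 CPM (SD, n = 4), a rise of 8.46 ± 1.21. Cxcl3, a neutrophil attractant, had no UMI in uninjured cord and was at least 623-fold higher against a floor of 3 counts over the group. Rises of 8.02 ± 0.64 for Tgm1, a transglutaminase, 7.97 ± 1.07 for Ccl2 and 7.75 ± 0.78 for Fosl1, an AP-1 subunit, were found. Of 15 monocyte and macrophage markers, 10 rose and 5 did not pass (12 adjusted over the list alone), among them the scavenger receptor Msr1 at 6.73 ± 0.65 (adjusted p = 1.7e-04 for the list, adjusted p = 0.456 with an estimated correlation). Cytokines and chemokines rose in 15 of 16 cases (15 adjusted over the list alone) and immediate early genes in 19 of 19 (19), with Ccn1 at 5.34 ± 0.47. The shifts of these lists had adjusted p = 2.4e-07 and 8.2e-14, and adjusted p = 0.374 and 0.286 with an estimated correlation. Interferon response genes rose in 11 of 15 cases (14 adjusted over the list alone), with the antiviral genes Isg15 at 3.48 ± 0.62 and Usp18 at 2.84 ± 0.61 (adjusted p = 3.7e-05 for the list, adjusted p = 0.456 with an estimated correlation). Some libraries share animals, so p-values are too small.

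Glial baseline transcripts fell at 24 h. Aspa (ENSMUSG00000020774), an enzyme of oligodendrocytes, went from 135 ± 9.3 to 34.8 ± 13.2 CPM (SD, n = 4), a log2 fold change of -1.95 ± 0.25, and Ugt8a, another such enzyme, was at -1.81 ± 0.13. Of 15 myelin and oligodendrocyte genes, 11 fell and 1 rose (11 and 1 adjusted over the list alone), with an adjusted p = 3.8e-05 (adjusted p = 0.392 with an estimated correlation). Oligodendrocyte precursor markers fell in 6 of 10 cases (6 adjusted over the list alone), among them Neu4 at -2.64 ± 0.33 and Gpr17 at -2.05 ± 0.46 (adjusted p = 5.3e-04 for the list, adjusted p = 0.181 with an estimated correlation). Astrocyte baseline markers fell in 8 of 13 cases (10 adjusted over the list alone), with the gap junction gene Gja1 at -2.12 ± 0.34 and the receptor gene Fgfr3 at -1.91 ± 0.26 (adjusted p = 8.1e-04 for the list, adjusted p = 0.456 with an estimated correlation). Homeostatic microglia markers were lower in 10 of 12 cases (10 lower and 1 higher adjusted over the list alone), with Siglech at -3.85 ± 0.54 and P2ry12 at -2.91 ± 0.24 (adjusted p = 3.7e-07 for the list, adjusted p = 0.18 with an estimated correlation). Libraries share animals, so these p-values are too small.

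Reactive astrocyte genes rose at 24 h in 13 of 16 cases (13 adjusted over the list alone). Among them were Lcn2, an iron-carrier protein gene, at 4.90 ± 0.75, the metalloproteinase inhibitor gene Timp1 at 4.62 ± 0.64 and the matrix gene Tnc at 4.07 ± 0.73. The list had an adjusted p = 4.2e-08, and adjusted p = 0.342 with an estimated correlation. Gfap itself was at -0.50 ± 0.26 and did not pass (adjusted p = 0.16, and 0.0468 without the 0.5 mm libraries of 72 h). Igfbp2 rose by 1.01 ± 0.25 to 72.9 ± 26 CPM (SD, n = 4, adjusted p = 0.0082), and Gap43 rose by 0.94 ± 0.11. Axon growth and nerve injury genes rose in 9 of 14 cases and fell in 2 (9 and 2 adjusted over the list alone), with the transcription factor gene Atf3 at 5.07 ± 0.32 and Sprr1a, a gene of regenerating axons, at 4.03 ± 0.76 (adjusted p = 5.6e-04 for the list, adjusted p = 0.236 with an estimated correlation). Hmox1 rose by 6.35 ± 0.60, and oxidative stress and metal genes rose in 8 of 12 cases and fell in 1 (8 and 2 adjusted over the list alone, adjusted p = 0.0013 for the list, adjusted p = 0.346 with an estimated correlation). Hbb-bs, a red blood cell transcript, was at 3875 ± 1823 CPM. At 24 h 2919 genes rose and 2512 fell of 15978 tested by edgeR, and of these 5431 genes 5380 were called in the same direction by DESeq2. A fit of the 8 libraries alone called 8269. Since libraries share animals, p-values are too small.

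The comparison of 72 h with uninjured cord asks what had changed by 3 days, the latest time collected. Proliferation, phagocyte and matrix genes rose and neuronal genes fell. Mki67 (ENSMUSG00000031004), a protein of dividing cells, went from 1.90 ± 0.756 to 71.9 ± 28.4 CPM (SD, n = 4), a rise of 5.35 ± 0.33. Of 18 cell cycle genes, 18 rose (18 adjusted over the list alone), with the DNA topoisomerase gene Top2a at 5.55 ± 0.46 and the mitotic ubiquitin-conjugating enzyme gene Ube2c at 5.4 ± 0.37 (adjusted p = 5.3e-14 for the list, adjusted p = 0.286 with an estimated correlation). Arg1 rose by 9.41 ± 1.23, Clec4d by 8.86 ± 1.19, Msr1 by 7.61 ± 0.66 and Lilr4b by 7.59 ± 0.80, all genes of myeloid cells. Of 15 monocyte and macrophage markers, 15 rose (15 adjusted over the list alone, adjusted p = 7.5e-07 for the list, adjusted p = 0.385 with an estimated correlation). Activated phagocyte genes rose in 12 of 13 cases (12 adjusted over the list alone), with the lectin Lgals3 at 5.23 ± 0.55 and the lysosomal protein Cd68 at 3.70 ± 0.27 (adjusted p = 5.3e-08 for the list, adjusted p = 0.286 with an estimated correlation). Animals are shared between libraries, which makes p-values too small.

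Extracellular matrix and antigen presentation genes rose at 72 h as well. Of 14 fibroblast and matrix genes, 13 rose and 1 fell (13 and 1 adjusted over the list alone), with the periostin gene Postn at 4.06 ± 0.52, the collagen crosslinking enzyme gene Lox at 4.04 ± 0.69 and Col3a1 at 3.65 ± 0.54, from 23.2 ± 3.04 to 256 ± 119 CPM (SD, n = 4). That list had an adjusted p = 2.4e-05, and adjusted p = 0.367 with an estimated correlation. Antigen presentation genes rose in 11 of 11 cases (11 adjusted over the list alone), with the class II gene H2-Ab1 at 3.15 ± 0.57 (adjusted p = 1.8e-04 for the list, adjusted p = 0.404 with an estimated correlation). Complement genes rose in 9 of 12 cases (9 adjusted over the list alone), C1qa at 2.55 ± 0.27 among them (adjusted p = 1.9e-04 for the list, adjusted p = 0.346 with an estimated correlation). Homeostatic microglia markers divided, with 8 of 12 higher and 3 lower (8 and 3 adjusted over the list alone, adjusted p = 0.0087 for the list, adjusted p = 0.397 with an estimated correlation, and 0.13 in white matter spots alone). Fcrls and Olfml3 were at 3.06 ± 0.23 and 2.60 ± 0.19. Haemoglobin transcripts were uneven at 72 h, at 7.75% of UMIs in replicate 3 and at 0.0424% to 0.247% in the other libraries. Spots of a cluster led by haemoglobin genes made up 1110 of 1304 spots of 72 h replicate 3. They also made up 763 of 1080 spots of 72 h replicate 2, likewise at 0.5 mm. Haemoglobin genes were left out of the genes used for clustering, so the name of the cluster does not make these spots blood. Hmox1 rose by 7.98 ± 0.65 and the ferritin gene Ftl1 by 3.75 ± 0.39. P-values are too small, since some libraries share animals.

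Neuronal transcripts fell at 72 h. Rbfox3, a nuclear protein gene of mature neurons, went from 93.6 ± 16.7 to 31.2 ± 16.1 CPM (SD, n = 4), a log2 fold change of -1.51 ± 0.29. Of 15 pan-neuronal genes 12 fell (12 adjusted over the list alone), and of 12 transmitter genes 9 fell (11 adjusted over the list alone), with the glycine receptor gene Glra1 at -2.27 ± 0.51. These lists had adjusted p = 1.8e-04 and 5.6e-04, and adjusted p = 0.456 and 0.456 with an estimated correlation. The choline transporter gene Slc5a7 was at -2.59 ± 0.34 and Chodl, another gene of motor neurons, at -2.81 ± 0.46. Myelin and oligodendrocyte genes were lower in 11 of 15 cases and higher in 2 (11 and 2 adjusted over the list alone), with Opalin at -1.34 ± 0.13 and the iron carrier gene Trf at 1.34 ± 0.21 (adjusted p = 0.0031 for the list, adjusted p = 0.456 with an estimated correlation, and 0.119 in gray matter spots alone). Cholesterol synthesis genes fell in 14 of 17 cases (14 adjusted over the list alone), with Hmgcs1 at -1.13 ± 0.13 and Lss at -1.04 ± 0.12 (adjusted p = 1.5e-06 for the list, adjusted p = 0.385 with an estimated correlation). With animals shared between libraries, p-values are too small.

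Igfbp2 rose at 72 h by 3.30 ± 0.27 to 333 ± 95.8 CPM (SD, n = 4, adjusted p = 6.2e-06). Of 16 reactive astrocyte genes, 16 rose (16 adjusted over the list alone), with Timp1 at 5.82 ± 0.68, Tnc at 4.72 ± 0.76 and Lcn2 at 4.42 ± 0.74 (adjusted p = 1.7e-07 for the list, adjusted p = 0.342 with an estimated correlation). Gfap was at 0.67 ± 0.27 with an adjusted p = 0.0492. That call ended without uninjured replicate 1 or 4 (adjusted p = 0.154 and 0.163). It also ended without 72 h replicate 1, 2 or 4 (0.155, 0.0919 and 0.126) and in a fit of the 8 libraries alone (0.192). Mean Gfap at 72 h was 3867 CPM at 1 mm (uninjured 1477) and 1230 CPM at 0.5 mm (uninjured 1426, n = 2 each). Astrocyte baseline markers fell in 7 of 13 cases and rose in 2 (8 and 2 adjusted over the list alone), with the neurotensin receptor gene Ntsr2 at -2.23 ± 0.50 and the glutamate transporter gene Slc1a3 at -1.35 ± 0.27. That list had an adjusted p = 0.0238, adjusted p = 0.543 with an estimated correlation, adjusted p = 0.062 without 72 h replicate 3, adjusted p = 0.0628 by fry, adjusted p = 0.0867 in gray matter spots alone and adjusted p = 0.274 without the 0.5 mm libraries of 72 h. Of 14 genes of the IGF axis, 7 rose and 1 fell (7 and 1 adjusted over the list alone), among them the binding protein gene Igfbp7 at 2.20 ± 0.25 (adjusted p = 0.0193 for the list, adjusted p = 0.342 with an estimated correlation, and 0.0751 in white matter spots alone). Gap43 rose by 0.71 ± 0.11 and Sprr1a by 5.69 ± 0.79. At 72 h 4581 genes rose and 4070 fell of 15978 tested by edgeR, and of these 8651 genes 8571 were called in the same direction by DESeq2. The count was 5392 without the 0.5 mm libraries of 72 h, a setting chosen after the data had been examined, and 4811 in a fit of the 8 libraries alone. P-values are too small because libraries share animals.

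**Figure D2:**
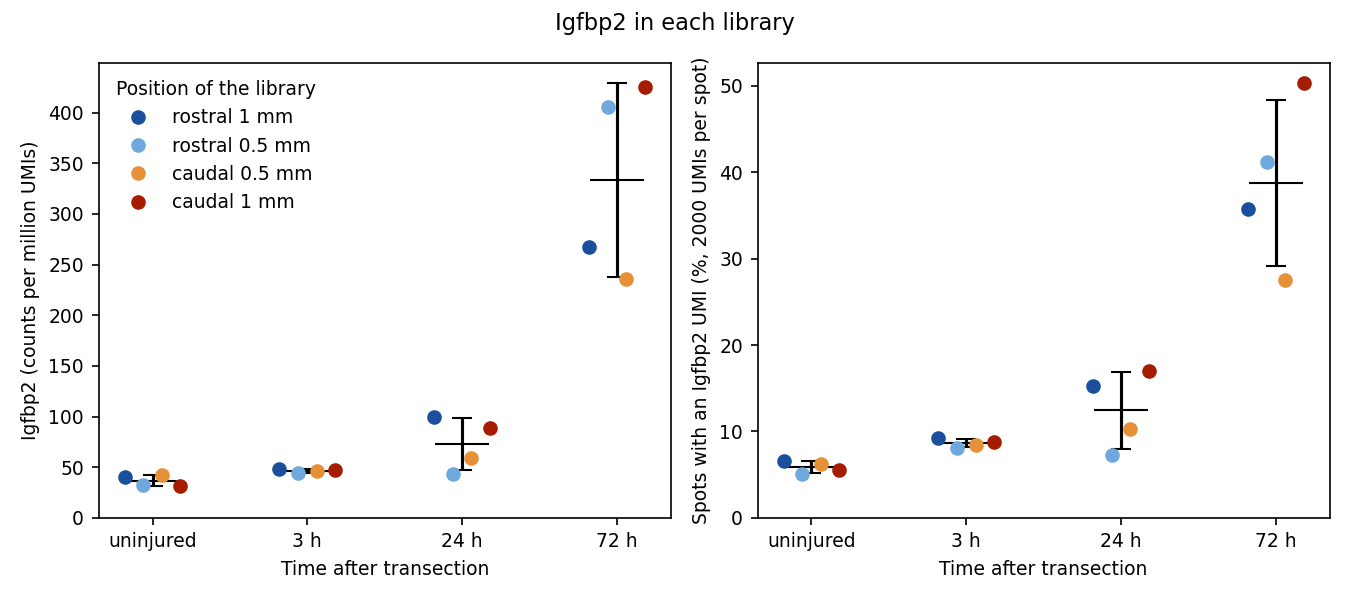
Igfbp2 in CPM over in-tissue UMIs (left vertical axis) and as the percentage of spots with an Igfbp2 UMI at 2000 UMIs per spot (right vertical axis) by time after transection (horizontal axis), with 1 point per library coloured by position, a dash at the mean of 4 libraries and bars of 1 SD. The 72 h libraries lie above those of the other times, with means of 333 CPM and 38.7% of spots.

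The comparison of 24 h with 3 h asks which transcripts differed between these times. No gene list was tested here, so the values are those of single genes. Arg1 rose by 8.83 ± 1.27, Msr1 by 6.38 ± 0.64, Tgm1 by 5.85 ± 0.54 and Sprr1a by 6.4 ± 0.92. Ccn5, a matricellular protein gene, rose by 5.54 ± 1.15. Falls were found for the small GTPase gene Arl4d at -4.11 ± 0.33, Csf3 at -3.91 ± 0.45, Myoc at -3.69 ± 0.83, Depp1 at -3.38 ± 0.35 and Cxcl1 at -3.06 ± 0.42, which went from 81.6 ± 14.8 to 10.5 ± 1.74 CPM (SD, n = 4). Gap43 rose by 0.87 ± 0.11, Gfap was at 0.48 ± 0.26 and Igfbp2 at 0.58 ± 0.25 (adjusted p = 0.198 and 0.103), while Igfbp2 passed without 24 h replicate 2 (adjusted p = 0.0249) and without the 0.5 mm libraries of 72 h (0.0436), and Gfap in a fit of the 8 libraries alone (0.0199). The edgeR test called 2382 genes higher and 1767 lower of 15978, and 4112 of these 4149 in the same direction by DESeq2. The count was 2698 and 2650 without 3 h replicates 2 and 3, 2485 without 24 h replicate 1, and 6926 without the 0.5 mm libraries of 72 h, a setting chosen after the data had been examined. Some libraries share animals, so p-values are too small.

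The comparison of 72 h with 24 h asks what set the latest time apart from the day before. No gene list was tested here either. Single genes of dividing cells that rose were Mki67 at 6.33 ± 0.35, Pbk at 6.20 ± 0.33, Ube2c at 5.93 ± 0.38 and Top2a at 5.47 ± 0.45. Gpnmb, a glycoprotein gene of phagocytes, rose by 5.33 ± 0.40. Single genes that fell were Csf3 at -4.34 ± 0.70, Fosb at -4.22 ± 0.49 and Il11 at -2.77 ± 0.66. Il1b was at -3.38 ± 1.08 (adjusted p = 0.0294), a call that ended without 24 h replicate 1 or 2 (adjusted p = 0.0517 and 0.09) or without 72 h replicate 2 or 4 (0.0962 and 0.0785). Igfbp2 rose by 2.28 ± 0.26 (adjusted p = 4.5e-05) and Gfap by 1.17 ± 0.27 (adjusted p = 0.0055), and Gap43 was at -0.23 ± 0.11 (adjusted p = 0.123). The edgeR test called 3372 genes higher and 2237 lower of 15978, and 5571 of these 5609 in the same direction by DESeq2. A fit of the 8 libraries alone called 1905, and in it the calls of Gfap and Il1b ended (adjusted p = 0.056 and 0.0807). Some libraries share animals, so p-values are too small.

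**Figure D3:**
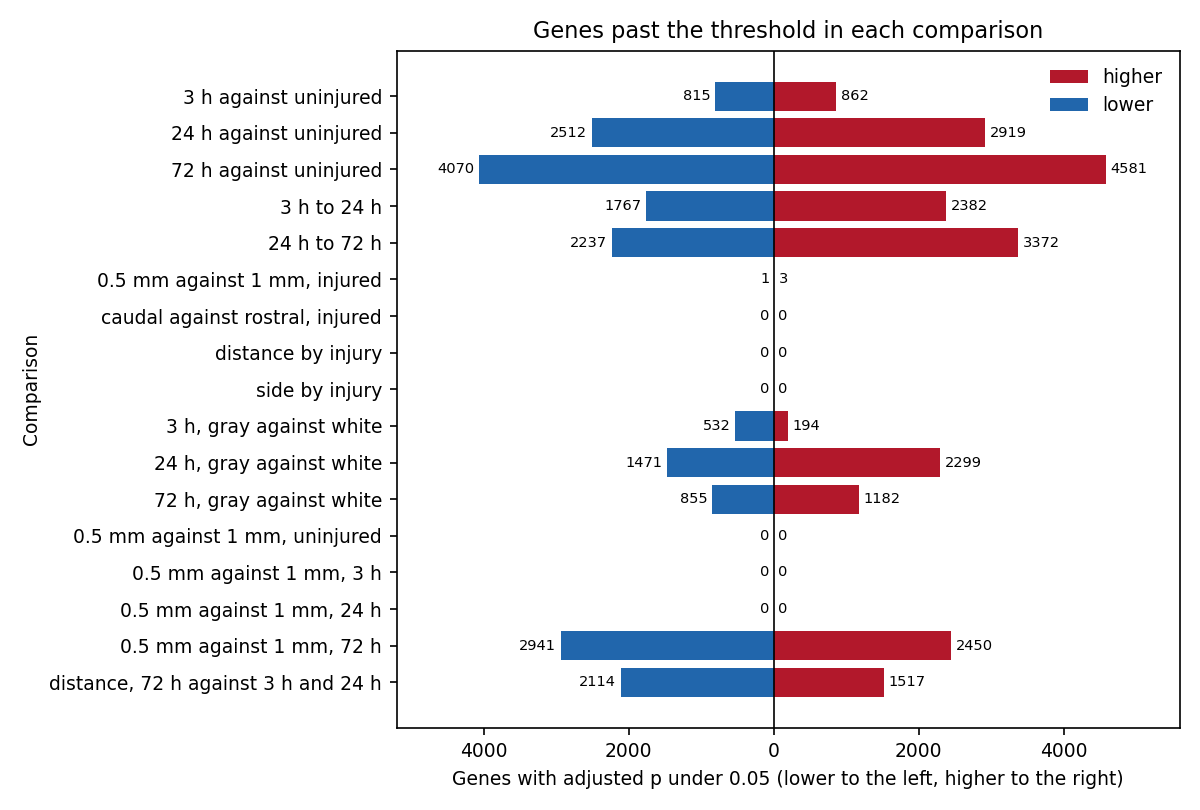
Number of genes past an adjusted p of 0.05 in edgeR (horizontal axis), with bars of lower genes to the left and of higher genes to the right of 0, for each of 17 comparisons (vertical axis). The largest bars belong to 72 h against uninjured cord, with 4581 higher and 4070 lower genes.

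Distance from the transection asks whether tissue at 0.5 mm differed from tissue at 1 mm after injury, over 6 injured libraries of each. Plk4, a kinase of centriole duplication, was higher at 0.5 mm by 1.26 ± 0.16 (adjusted p = 0.0416) and Cchcr1, a centrosomal protein gene, was at -0.95 ± 0.11 (adjusted p = 0.0407). Cenpf, a mitotic kinetochore gene, and C730034F03Rik, which were singled out after their values had been seen, were higher by 1.06 ± 0.13 and 1.99 ± 0.24. Gfap stood at -1.14 ± 0.19 and did not pass (adjusted p = 0.0685, and 3.2e-06 in DESeq2), nor did Igfbp2 at -0.30 ± 0.21 (adjusted p = 0.384). These 4 genes, 3 higher and 1 lower, were the ones past the threshold in edgeR of 15606 tested, with 3889 at an unadjusted p under 0.05, and DESeq2 called 1621. The count fell to 0 without any of 3 h replicates 1, 2 and 4, 24 h replicates 1, 2 and 4 or 72 h replicates 1, 3 and 4, to 1 without 3 h replicate 3, and was 1363 over all 16 libraries and 0 after thinning to the shallowest library. It was 116 without 72 h, 63 of them higher, in a setting chosen after the data had been examined. Libraries share animals in a way not stated, so p-values may be too small or too large.

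Within each time, the distance was tested after the data had been examined, with 2 libraries of each distance. At 72 h neuronal and astrocyte baseline transcripts were lower at 0.5 mm. Tac2 (ENSMUSG00000025400), which encodes a tachykinin of dorsal horn neurons, was at 0.241 CPM at 0.5 mm and 42.3 CPM at 1 mm (means of 2 libraries), a log2 fold change of -7.25 ± 0.52, and Camkv, a neuronal vesicle protein gene, was at -5.21 ± 0.24. Gfap was at 1230 against 3867 CPM, a log2 fold change of -1.53 ± 0.27 (adjusted p = 0.0019), while Igfbp2 was at 0.01 ± 0.27. Lower at 0.5 mm were 10 of 12 transmitter genes (median -2.06), 11 of 13 astrocyte baseline markers (median -1.44) and 8 of 15 pan-neuronal genes (median -1.17). Reactive astrocyte genes went the other way, with 8 of 16 higher and 2 lower at 0.5 mm (median 0.66). Higher were 12 of 15 monocyte and macrophage markers (median 1.77), 10 of 16 cytokines and chemokines (median 2.51), 16 of 18 cell cycle genes (median 1.09) and 5 of 6 red blood cell genes (median 5.63), of which Hba-a1 lost the call without 72 h replicate 1, 3 or 4 (adjusted p = 0.0983, 0.16 and 0.0505). The red blood cell difference rested mostly on 72 h replicate 3, where Hba-a1 was at 19392 CPM, against 613 CPM in replicate 2 and 89.2 and 252 CPM in replicates 1 and 4. At 72 h 2450 genes were higher and 2941 lower in edgeR. Fewer, above all higher ones, passed without replicate 1 or 3 (1 library left at that distance). At 72 h 3631 genes had a difference unlike that at 3 h and 24 h, fewer without these libraries. In uninjured cord, at 3 h and at 24 h edgeR called 0, 0 and 0 genes, with 572, 2930 and 1875 at an unadjusted p under 0.05, and DESeq2 called 1, 266 and 99. At 24 h the edgeR count was 14 and 14 without 72 h replicates 2 and 3. Animals are shared, so p-values may err either way.

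**Figure D4:**
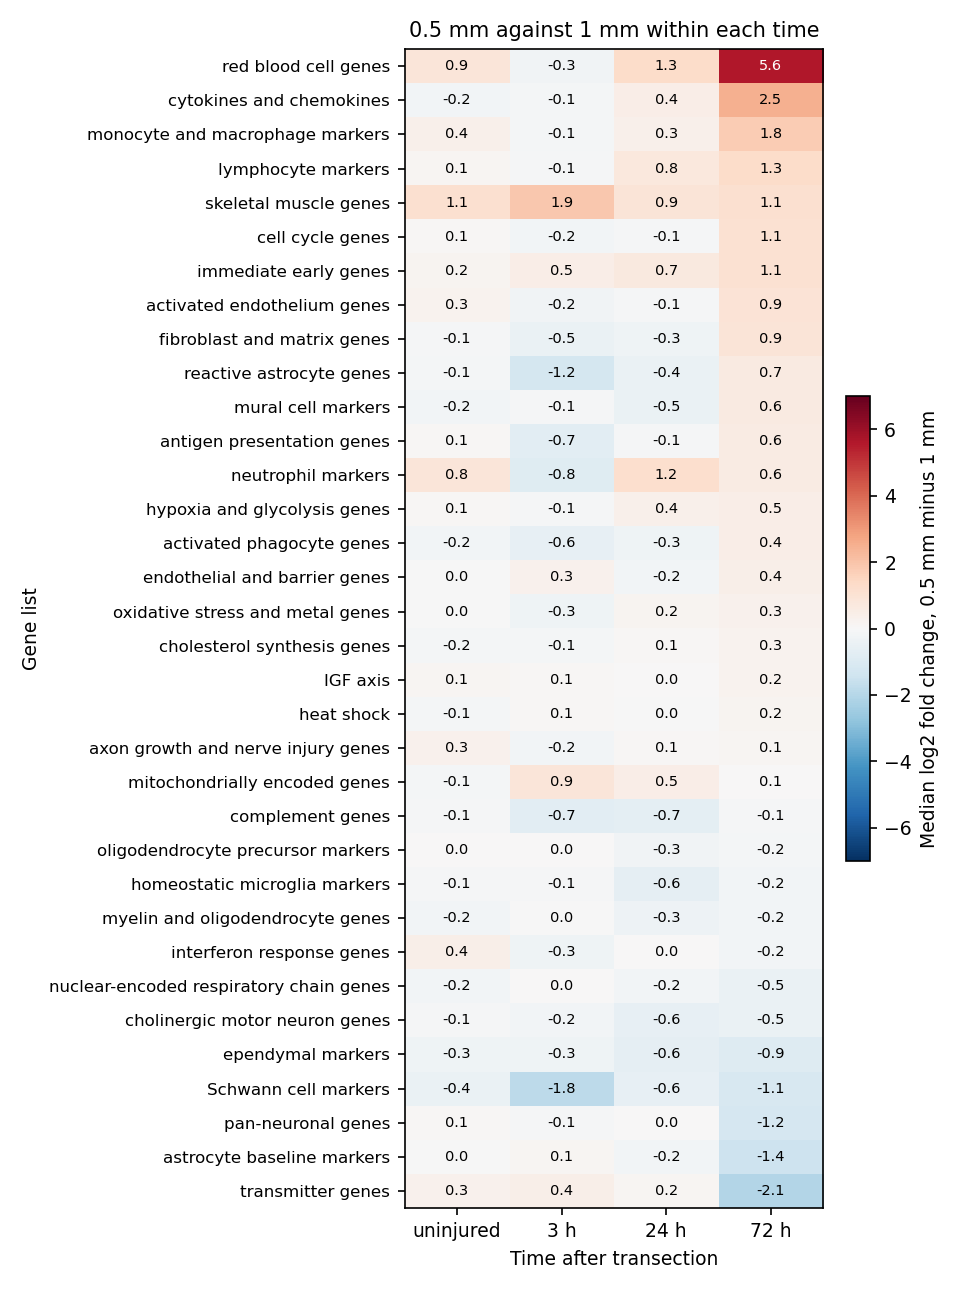
Median log2 fold change of 0.5 mm minus 1 mm (colour) for each gene list (vertical axis) in uninjured cord and at 3 h, 24 h and 72 h (horizontal axis), from 2 libraries per distance and time. At 72 h transmitter genes lie at -2.06 and red blood cell genes at 5.63.

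The side of the transection asks whether caudal and rostral tissue differed after injury, over 6 injured libraries of each. No gene of 15606 passed in edgeR (455 at an unadjusted p under 0.05, smallest adjusted p = 0.228), and DESeq2 called 11. Igfbp2 was at 0.02 ± 0.21, Gfap at -0.14 ± 0.19 and Gap43 at -0.32 ± 0.10 caudal against rostral, with adjusted p of 1.0 or close to it in each case. Without 3 h replicate 2 the count was 1. For a distance difference that depends on injury, edgeR called 0 of 15978 genes (347 at an unadjusted p under 0.05) and DESeq2 called 1, and for a side difference that depends on injury edgeR called 0 (75 at an unadjusted p under 0.05) and DESeq2 called 0. In simulated data with 2-fold changes, these injury tests recovered 15% and 20% of changed genes, against 70% for side. Animals are shared, so p-values may err either way.

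The comparison of gray matter with white matter asks whether the change at a time differed between these regions, with 4 libraries at each time and 3 at 72 h. The classes covered less of the tissue at 72 h, where replicate 2 gave 208 gray and 28 white spots and had 763 spots in the cluster led by haemoglobin genes, against 595 to 815 gray and 434 to 515 white spots in uninjured libraries. At 3 h immediate early genes rose less in gray than in white matter, and 14 of 19 had a lower change there (median difference -1.74). Egr1, a transcription factor gene of this list, went from 37.3 ± 8.28 to 266.9 ± 74.6 CPM in gray matter and from 8.49 ± 0.97 to 394.5 ± 101 CPM in white matter (SD, n = 4), a difference of -2.71 ± 0.16, and Sphk1 and Egr3 were at -2.93 ± 0.24 and -2.62 ± 0.29. The intermediate filament gene Vim, at 1.37 ± 0.20, and the smooth muscle gene Tagln, at 2.44 ± 0.30, had higher changes in gray matter, mainly through falls in white matter. Vim was at 66.0 and then 67.4 CPM in gray matter, and went from 387 to 148 CPM in white matter. Tagln went from 10.1 to 12.8 CPM in gray matter and from 78.6 to 17.7 CPM in white matter. A positive difference thus need not mean a rise in gray matter. At 24 h changes were higher in gray matter for 16 of 17 cholesterol synthesis genes (median 0.82), 13 of 15 myelin and oligodendrocyte genes (median 0.63), 9 of 12 complement genes (median 1.07) and 10 of 13 astrocyte baseline markers (median 0.49). Lpl, a lipase of lipid uptake, was at 2.55 ± 0.18 and Deptor, an inhibitor of mTOR, at 1.96 ± 0.22. Deptor fell in both regions, from 18.4 to 14.6 CPM in gray matter and from 18.8 to 4.37 CPM in white matter. Lower changes were found for Ccn2 at -2.33 ± 0.17 and Hmga1 at -2.24 ± 0.18. Heat shock genes had lower changes in gray matter in 7 of 12 cases (median -0.56). Some libraries share animals.

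Phagocyte and astrocyte genes differed between the regions at 72 h. Homeostatic microglia markers had higher changes in gray matter in 12 of 12 cases (median 0.85), reactive astrocyte genes in 12 of 16 (median 1.08) and interferon response genes in 9 of 15 (median 1.04). The adhesion receptor gene Cd44 was at 2.07 ± 0.25, and Spp1, which encodes osteopontin, was at -1.73 ± 0.17. Spp1 rose in both regions, from 213 ± 51.0 to 2072 ± 2123 CPM in gray matter and from 66.2 ± 9.07 to 1833 ± 1342 CPM in white matter. Gfap went from 844 ± 128 CPM in uninjured gray matter to 3212 ± 1550 CPM at 72 h, and from 2520 ± 282 to 3522 ± 1636 CPM in white matter (SD, n = 4 and 3). Its regional difference in change was -0.56 ± 0.13 at 3 h, 1.12 ± 0.13 at 24 h and 1.47 ± 0.14 at 72 h, of which the first was not called at a clustering resolution of 1 (adjusted p = 0.0969) or with library as a random block (0.364). Gap43 stood at 0.04 ± 0.14, -1.15 ± 0.12 and -0.82 ± 0.14. Igfbp2 rose to 560.4 ± 237 CPM in gray matter and to 202.8 ± 86.6 CPM in white matter at 72 h. No regional difference in its change passed at any time (0.36 ± 0.32, -0.02 ± 0.28 and 0.39 ± 0.29, edgeR adjusted p = 0.62, 0.979 and 0.403). With these SEs a difference is not ruled out, and separate fits gave 4.02 in gray and 3.21 in white matter at 72 h. Of 14920 genes, edgeR called 194 higher and 532 lower at 3 h, 2299 higher and 1471 lower at 24 h, and 1182 higher and 855 lower at 72 h. This balance depended on the processing. At a clustering resolution of 0.3 the 24 h calls were 1574 higher and 2204 lower, and the 72 h calls were 2087 higher and 346 lower at a resolution of 1 and 1829 higher and 414 lower with a filter at 10 CPM. The 72 h count of 2037 was 1289 without uninjured replicate 2 and 1173 and 720 without 72 h replicates 1 and 4, after thinning the counts were 43, 307 and 155, and limma with library as a random block called 445 at 3 h and 1276 at 72 h. DESeq2 shared 609, 3023 and 1607 calls of the same direction, with 16.5%, 50.2% and 59.8% of its calls higher in gray matter against 26.7%, 61% and 58.0%. Some libraries share animals, so p-values are too small.

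**Figure D5:**
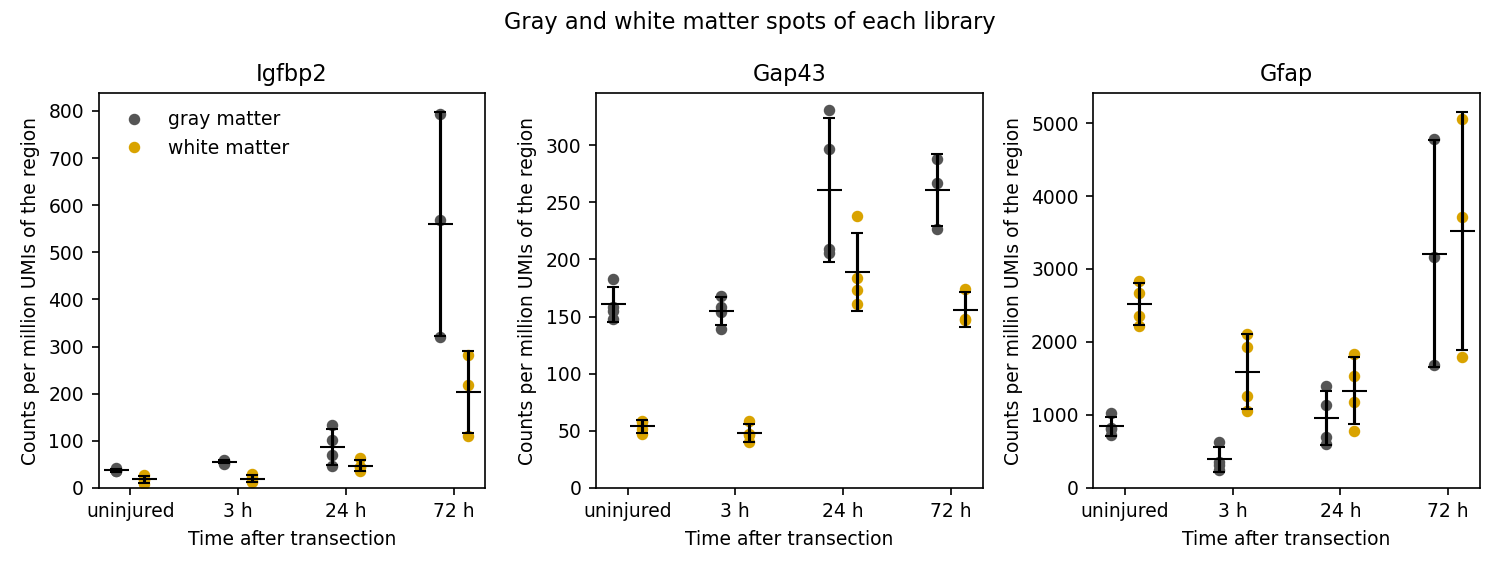
CPM of Igfbp2, Gap43 and Gfap (vertical axis, 1 panel per gene) in gray and white matter spots by time after transection (horizontal axis), with 1 point per library, the mean and bars of 1 SD. Igfbp2 reaches 560.4 CPM in gray and 202.8 CPM in white matter at 72 h.

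The share of spots with Igfbp2 asks how widely the transcript was found, after each spot had been thinned to 2000 UMIs. The share was 5.88 ± 0.653% in uninjured cord, 8.66 ± 0.495% at 3 h, 12.4 ± 4.46% at 24 h and 38.7 ± 9.61% at 72 h (SD, n = 4 libraries). It was higher in 4 of 4 libraries at each time, with 2-sided exact permutation p = 0.0286 and adjusted p = 0.0286 each, the smallest p that 4 against 4 libraries can give. This test exchanges libraries freely over positions, and exchange within positions would give 8 splits, too few to pass. At 1000 UMIs per spot the differences were 0.49, 3.33 and 20.8 percentage points (exact permutation adjusted p = 0.514, 0.129 and 0.0857), and without thinning 2.82, 21.0 and 52.2 points (0.6, 0.171 and 0.0857). In both settings the exact p at 72 h was the smallest possible, and adjustment over 3 times kept it from passing. At 4000 UMIs per spot the differences were 3.26, 10.2 and 44.6 points, each at adjusted p = 0.0286. No background was subtracted. Outside tissue Igfbp2 was at 116 CPM in 24 h replicate 4 and 260 CPM in 72 h replicate 4, against 89 and 425 CPM in tissue, so a UMI in a spot need not stem from its cells. Co-occurrence asks which transcripts shared spots with Igfbp2. At 72 h the mean Spearman correlation over spots was 0.195 ± 0.0832 with the neuronal gene Snap25, 0.138 ± 0.105 with the astrocyte water channel gene Aqp4, 0.105 ± 0.136 with Gfap, -0.179 ± 0.14 with Vim and -0.25 ± 0.0926 with the myelin gene Mbp (SD, n = 4), against 0.0468, -0.000404, -0.0345, 0.0057 and -0.0544 in uninjured cord. None of 24 such differences passed the exact permutation test after adjustment (smallest adjusted p = 0.137, smallest exact p = 0.0286). A ranking of 4862 genes by their lowest correlation with Igfbp2 in the 72 h libraries, from a separate draw of the whole profile at 4000 UMIs per spot and made after the data had been examined, put Snap25 in place 1 (0.210 to 0.444), Nat8l in place 2, Aqp4 in place 3, Gfap in place 3925 and Mbp in place 4862. The place of Gfap rested on 72 h replicate 1, since its correlation was -0.0612 there and 0.197, 0.377 and 0.0766 in replicates 2 to 4. Without thinning, where depth enters, the mean correlation at 72 h was 0.495 ± 0.0596 for Gfap and 0.599 ± 0.0756 for Snap25. A spot holds several cells, so these values do not say which cells held Igfbp2, and libraries share animals, so p-values are too small.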

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

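The distance test within each time, the tests of it, the dilution, depth and tissue-mix tests and the fits without the 0.5 mm libraries of 72 h were chosen only after the results had been seen, while the tests on C1q and on meningeal markers and the splits were chosen before.

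More genes differed between 0.5 mm and 1 mm at 72 h than at 3 h or 24 h, and 3631 genes had a distance difference at 72 h unlike that at 3 h and 24 h. Of the 5391 genes at 72 h, 2246 were called without 72 h replicate 3, whose matrix had been exported again. That left 1 library at 0.5 mm, with the spread taken from the other groups, so the part of that library stays open. Thinning to the shallowest library left 4734, which argues against unequal depth. Haemoglobin, at its share in the 72 h libraries, can lower other genes by 0.116 at most on the log2 scale. The absolute log2 fold changes of the called genes began at 0.30 with a lower quartile of 0.65. With 2 libraries per distance a gene shifted by 0.116 could hardly be called, yet 5391 genes were called. This argues against dilution by red cell RNA as the main cause of the calls. The size of the count depends on 72 h replicate 1 too. Differences between animals and in the true distance of the sections from the transection were not tested and stay open, and no biological explanation was tested.

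Homeostatic microglia markers were lower at 3 h than in uninjured cord, with a list median of -2.12 (members -3.56 to -0.97). Haemoglobin, at its share in the 3 h libraries, can lower other genes by 0.0316 at most on the log2 scale, which argues against dilution by red cell RNA. After thinning the median was -2.08 (members -3.66 to -0.95), which argues against unequal depth. Fewer microglia would lower all their transcripts alike, but C1qa, C1qb and C1qc rose by 0.567 relative to the homeostatic markers, with the 3 h libraries at 2.28 to 3.03 and the uninjured libraries at 1.94 to 2.21. C1qa, C1qb and C1qc themselves were at -1.47, -1.13 and -1.43, so fewer microglia for part of the fall stays open, as do differences between animals. These values are consistent with a lower level of homeostatic transcripts per microglial cell, which remains a hypothesis.

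Igfbp2 was higher at 72 h than in uninjured cord, by 3.30 on the log2 scale. After thinning the rise was 3.33, which argues against unequal depth. It was 4.02 in gray and 3.21 in white matter spots alone, without the meninges cluster. That argues against another mix of the regions and against meningeal tissue as the whole cause. The median of the mean rank correlations of 7 meninges and nerve root markers with Igfbp2 over spots was -0.0627 (members -0.0973 to 0.107, Ptgds and Mgp positive). A median below 0 was the bound set beforehand against meningeal tissue, but members went both ways, so a part from it stays open. Which cells held the transcript and whether animals differed stay open, and no biological explanation was tested.

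The splits of the libraries into other groups were counted for each fit. They exchange libraries freely over positions and animals, although position enters the fits and libraries share animals. Chance is excluded below only for such free exchange, and a chance difference between animals is not excluded. Exchanges that keep position would give 8 splits for a pair of times, too few for a share under 0.05. For 3 h, 24 h and 72 h against uninjured cord, 1 of 35 splits gave as many genes as the real 1677, 5431 and 8651. The highest of the others gave 1, 0 and 5772, so that chance can be excluded for free exchange alone. The split with 5772 genes set uninjured replicates 1 to 3 and 72 h replicate 1 against the others. From 3 h to 24 h and from 24 h to 72 h, 1 of 35 splits gave as many as the real 4149 and 5609. The highest others were 1 and 819, and chance can be excluded for free exchange alone. For the change between gray and white matter at 3 h, 24 h and 72 h, 1 of 35 splits gave as many as the real 726, 3770 and 2037. The highest others were 7, 70 and 538, and chance can be excluded for free exchange alone. For distance, 2 of 100 splits gave at least the real 4 genes, the real one included, so that chance can be excluded only for exchange that ignores time and side, and the call stays weak, since leaving out any of 9 libraries brought the count to 0. The other gave 185, many times the real count. It set 3 h replicate 1, 24 h replicates 1 to 3 and 72 h replicates 2 and 3 against the others. That split kept the 72 h libraries grouped by distance, and 5391 genes differed by distance at 72 h. For side, and for the dependence of distance and of side on injury, the real count was 0, which 99 of 99, 91 of 91 and 91 of 91 splits reach by necessity, so that these splits say nothing about chance. Their highest others were 12, 4610 and 6854 genes, of which the last pair points to a structure of the samples. For list shifts at 3 h and 24 h, 3 of 35 and 8 of 35 splits gave as many as the real 20 and 16, with 20 and 21 as the highest others, and chance cannot be excluded. At 72 h, 1 of 35 splits gave as many as the real 26, with 25 as the highest other. For free exchange, chance can be excluded by a margin of 1 list only, and all 26 shifts were lost with an estimated correlation. Some libraries share animals, which the splits do not undo.

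Some libraries lay far from the other 3 of their time, in 15 of 216 groups of 4 libraries, where chance gives about 1 in 20 groups, or 10.8. Uninjured replicate 3 had 9065388 UMIs (others 18973800 to 20312236) and 18344 genes with a UMI (others 19226 to 19400). Its mean log2 CPM was 3.23 for activated endothelium genes (others 2.87 to 2.93) and 1.91 for skeletal muscle genes (others 1.01 to 1.08). Gap43 was at 152.5 CPM in uninjured replicate 2 (others 114 to 118) and at 106.4 CPM in 3 h replicate 4 (others 127 to 129). The 10 most abundant genes took 9.11% of UMIs in 24 h replicate 1 (others 12.2% to 12.6%), and there Igfbp2 had a rank correlation of 0.102 with Aqp4 (others 0.0146 to 0.0247) and of 0.172 with Snap25 (others -0.0233 to -0.00341). Fibroblast and matrix genes were at a mean log2 CPM of 4.66 in 24 h replicate 2 (others 5.37 to 5.44) and skeletal muscle genes at 1.74 in 24 h replicate 3 (others 0.959 to 1.08). In 72 h replicate 3 haemoglobin took 7.75% of UMIs (others 0.0424% to 0.247%), the 10 most abundant genes took 16.1% (others 9.95% to 10.6%), and Schwann cell markers were at a mean log2 CPM of 1.36 (others 3.99 to 4.33). Oligodendrocyte precursor markers were at 5.28 in 72 h replicate 1 (others 4.89 to 4.95).

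Changes that differed between gray and white matter, by a test of the difference, numbered 726, 3770 and 2037 genes at 3 h, 24 h and 72 h. Among them were Gfap at -0.56, 1.12 and 1.47 in that order, and Gap43 at -1.15 at 24 h and -0.82 at 72 h. In the capture areas for which spots outside tissue were deposited, these held 5550158 UMIs in 24 h replicate 4 and 7795737 UMIs in 72 h replicate 4, data which the comparisons did not use. Over genes above 10 CPM their profile correlated with that of the spots in tissue at r = 0.967 and 0.971, a correlation across genes, which are not independent replicates.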

How the results depend on the processing

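The fits without 72 h or without its 0.5 mm libraries and the distance tests within each time were chosen only after the results had been seen. Of the values named for single genes, 7402 kept their side of the threshold over the alternatives run, 417 lost the call, 14 gained it and 4 reversed. A changed sign was counted as reversed only where 1 of the settings compared gave a call. By the same rule, 2084 list values kept their side of the threshold, 133 lost the call, 26 gained it and 1 reversed. Of the summary values, 411 kept their call, stayed within 1.5 times the count or, for shares with a library left out, moved by less than 1 SD. Another 66 moved, 6 lost the call and 1 gained it. The 264 correlations counted as unchanged stayed short of the threshold at other depths, or moved by less than 1 SD with a library left out, where no test was run. Tests of this size over a family of 24 could hardly pass. Where no cause is named, the cause was not tested.

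In fits of the 8 libraries compared alone, the counts were 3162 at 3 h, 8269 at 24 h and 4811 at 72 h against uninjured cord and 1905 from 24 h to 72 h, and the change of Igfbp2 at 3 h passed at 0.47 (adjusted p = 0.006). Without the 0.5 mm libraries of 72 h they were 3192 at 3 h, 5392 at 72 h and 6926 from 3 h to 24 h. Gray matter spots alone gave 1071 genes at 3 h and white matter spots alone 3400 at 72 h. A 2-fold minimum, which leaves fewer genes by construction, gave 798, 2024 and 3878 at 3 h, 24 h and 72 h, 1470 and 2277 between successive times, 194, 679 and 317 for the regional differences at 3 h, 24 h and 72 h, and 2624 and 2192 for distance at 72 h and its difference from 3 h and 24 h. For distance after injury DESeq2 called 1621, all 16 libraries gave 1363, the fit without 72 h gave 116 and thinning gave 0. DESeq2 called 11 genes for side, 1 for the dependence of distance on injury, and 1, 266 and 99 for distance in uninjured cord, at 3 h and at 24 h, where no filter on low counts gave 1 and 18 in uninjured cord and at 3 h. Thinning left 43, 307 and 155 regional differences, where fewer counts are the construction, and limma-voom with library as a random block gave 445 at 3 h and 1276 at 72 h. An estimated correlation left 1 of 62 list shifts. The Igfbp2 share differed by 0.49, 3.33 and 20.8 points at 1000 UMIs per spot and by 2.82, 21.0 and 52.2 points without thinning. None passed, although at 72 h the exact p was the smallest possible, so these tests were too small to end that call. Removal of mitochondrially encoded and haemoglobin genes moved the share of regional calls at 72 h that were higher in gray matter from 58.0% to 75.7%, and no scaling moved the median of all genes by 0.1 on the log2 scale.

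Reversed values after thinning were -2.16 for S100a4 at 3 h and -1.42 and -1.45 for Tgm1 at 24 h and 72 h in the regional difference. The others were -3.49 for Pirt in distance at 72 h without 72 h replicate 2 (up to 6.84 with another library left out) and -0.34 for cholesterol synthesis genes at 24 h in white matter spots alone (adjusted p = 0.0181), against 0.46 in gray matter spots alone (adjusted p = 1.2e-04).

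With each library left out in turn, the counts ranged from 944 to 1374 at 3 h, 3844 to 4867 at 24 h and 6653 to 9684 at 72 h, from 2485 to 3970 for 3 h to 24 h and from 3879 to 7375 for 24 h to 72 h. They ranged from 0 to 3 for distance, 0 to 1 for side, 0 to 0 for both dependences on injury, 536 to 746, 2988 to 3649 and 720 to 1981 for the regional differences, 0 to 1, 0 to 0, 0 to 14 and 1685 to 6076 for distance in uninjured cord, at 3 h, 24 h and 72 h, and 1273 to 4291 for its difference at 72 h. Igfbp2 ranged from 0.31 to 0.62, 0.84 to 1.27 and 3.06 to 3.47 at 3 h, 24 h and 72 h, list shifts from 56 to 65, and the Igfbp2 share from 2.52 to 3.01, 5.04 to 8.27 and 29.0 to 36.6 points. The share values with a library left out carry no test. Depth limits what was tested, since 15978 of 32285 genes had the counts that the filter for the times asks.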

Other observations

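The tests of this part were chosen before the results had been seen, except the naming of the clusters of spots and the fits without the 0.5 mm libraries of 72 h. Numbers in brackets after a count are those adjusted over the list alone. Stress and blood cell lists not yet described rose at 3 h. Of 12 heat shock genes 4 rose (5), with the small chaperone gene Hspb1 at a log2 fold change of 2.22 ± 0.44, and of 11 neutrophil markers 5 rose (6), with the decoy receptor gene Il1r2 at 2.83 ± 0.56. Of 6 red blood cell genes 5 rose (5), of 8 skeletal muscle genes 3 rose (5), with Acta1 at 1.21 ± 0.21, of 3 lymphocyte markers 1 rose (3), of 14 axon growth and nerve injury genes 3 rose (3), with Atf3 at 6.67 ± 0.33, and of 12 nuclear-encoded respiratory chain genes 2 rose (3). Camera adjusted p was 2.2e-05, 0.01, 2.2e-05, 5.0e-04, 0.0129, 0.02 and 0.0076 in that order, and adjusted p = 0.0943, 0.456, 0.346, 0.366, 0.367, 0.346 and 0.535 with an estimated correlation. Of 10 mitochondrially encoded genes 0 passed (0) while the list shifted up at adjusted p = 0.0193 (adjusted p = 0.582 with an estimated correlation). Oligodendrocyte precursor markers fell in 1 of 10 cases (2), mural cell markers in 1 of 8 (2) and fibroblast and matrix genes in 2 of 14 (6), with Col3a1 at -2.54 ± 0.55, at adjusted p = 0.0127, 0.0381 and 0.0381, and adjusted p = 0.332, 0.456 and 0.562 with an estimated correlation. Leaving out 1 library ended the calls for neutrophil markers (adjusted p = 0.0528 without uninjured replicate 1 and 0.0505 without 3 h replicate 4), axon growth (0.121 without uninjured replicate 1), respiratory chain (0.123 without 3 h replicate 3), mitochondrially encoded genes (0.104, 0.147 and 0.397 without uninjured replicates 2 and 3 and 3 h replicate 2), mural cells (0.0528, 0.0548 and 0.101 without uninjured replicate 1 and 3 h replicates 1 and 4) and fibroblasts (0.0811, 0.163 and 0.0703 without uninjured replicate 1, 3 h replicate 3 and 72 h replicate 3). Lists without a shift at 3 h were monocyte and macrophage markers (2 higher and 2 lower of 15), IGF axis (1 and 2 of 14), myelin and oligodendrocyte genes (0 and 1 of 15), cholinergic motor neuron genes (0 of 8), ependymal markers (0 of 9), Schwann cell markers (0 of 7), cell cycle genes (1 and 0 of 18), interferon response genes (0 and 1 of 15), antigen presentation genes (0 of 11) and hypoxia and glycolysis genes (2 and 1 of 13), with adjusted p of 0.0934 to 0.898. The myelin list passed without 3 h replicate 2 (0.0059). Calls also ended in gray matter spots alone for neutrophil markers (0.059), lymphocyte markers (0.071), axon growth (0.108), mural cells (0.185), fibroblasts (0.0827) and skeletal muscle (0.0657). In white matter spots alone they ended for neutrophil markers (0.0523), lymphocyte markers (0.0895), oligodendrocyte precursors (0.0519), fibroblasts (0.144), mitochondrially encoded genes (0.122) and respiratory chain (0.0605). By fry they ended for neutrophil markers (0.0988), mural cells (0.051), fibroblasts (0.173), mitochondrially encoded genes (0.29) and respiratory chain (0.176), and without the 0.5 mm libraries of 72 h for fibroblasts (0.0542). P-values are too small, since some libraries share animals.

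At 24 h heat shock genes rose in 8 of 12 cases (9), with Hspb1 at 4.07 ± 0.47, neutrophil markers in 6 of 11 (7), with Cxcr2 at 4.39 ± 0.82, activated endothelium genes in 7 of 11 (7), with Esm1 at 3.36 ± 0.74, antigen presentation genes in 5 of 11 (6), with the peptide transporter gene Tap1 at 1.83 ± 0.39, and red blood cell genes in 5 of 6 (5). Camera adjusted p was 1.9e-04, 0.0016, 0.01, 0.0087 and 0.0084, and adjusted p = 0.116, 0.404, 0.487, 0.491 and 0.456 with an estimated correlation. Lists without a shift at 24 h were activated phagocyte genes (4 higher and 3 lower of 13), lymphocyte markers (2 and 0 of 3), IGF axis (4 and 3 of 14), pan-neuronal genes (0 and 1 of 15), transmitter genes (0 and 1 of 12), cholinergic motor neuron genes (0 and 2 of 8), endothelial and barrier genes (3 and 7 of 14), mural cell markers (1 and 3 of 8), fibroblast and matrix genes (4 and 2 of 14), ependymal markers (0 and 3 of 9), Schwann cell markers (0 and 1 of 7), skeletal muscle genes (1 and 0 of 8), cell cycle genes (6 and 0 of 18), complement genes (2 and 2 of 12), cholesterol synthesis genes (3 and 2 of 17), hypoxia and glycolysis genes (3 and 2 of 13), mitochondrially encoded genes (0 of 10) and nuclear-encoded respiratory chain genes (1 and 0 of 12), with adjusted p of 0.0597 to 0.884. Some of these passed without 1 library, namely lymphocyte markers (adjusted p = 0.0497, 0.0472, 0.0482, 0.0491 and 0.0422 without uninjured replicate 4, 3 h replicates 1 and 3 and 24 h replicates 1 and 4), cell cycle genes (0.0192 and 0.0375 without uninjured replicate 1 and 24 h replicate 3), endothelial and barrier genes (0.0383 and 0.0387 without uninjured replicate 3 and 24 h replicate 4), motor neuron genes (0.0342 without 24 h replicate 4) and pan-neuronal genes (0.0421 without 72 h replicate 3). Pan-neuronal genes also passed in gray matter spots alone (0.0226) and without the 0.5 mm libraries of 72 h (0.0105), and transmitter genes in gray (0.0301) and in white matter spots alone (0.0352) and without those libraries (0.0056). Cholesterol synthesis genes were higher in gray matter spots alone (0.46, adjusted p = 1.2e-04) and lower in white matter spots alone (-0.34, adjusted p = 0.0181). By fry, lymphocyte markers (0.0046), endothelial and barrier genes (0.0071), mural cell markers (0.0209) and ependymal markers (0.021) passed. The call for antigen presentation genes ended by fry (0.051) and in white matter spots alone (0.102). With animals shared between libraries, p-values are too small.

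At 72 h immediate early genes rose in 13 of 19 cases and fell in 1 (13 and 1), cytokines and chemokines rose in 15 of 16 (15), with Ccl2 at 7.49 ± 1.08, neutrophil markers in 6 of 11 (7), activated endothelium genes in 8 of 11 (8), with Selp at 4.98 ± 1.12, and mural cell markers in 4 of 8 (4), with the contractile gene Tagln at 3.65 ± 0.58. Camera adjusted p was 0.0031, 0.003, 0.0193, 0.0058 and 0.027, and adjusted p = 0.539, 0.518, 0.456, 0.456 and 0.418 with an estimated correlation. Axon growth and nerve injury genes rose in 9 of 14 cases and fell in 2 (9 and 2), oxidative stress and metal genes rose in 9 of 12 (9), interferon response genes in 10 of 15 (11), with Bst2 at 2.61 ± 0.32, and red blood cell genes in 5 of 6 (5), at adjusted p = 0.01, 4.9e-04, 0.01 and 0.0361, and adjusted p = 0.286, 0.342, 0.543 and 0.501 with an estimated correlation. Cholinergic motor neuron genes fell in 4 of 8 cases (4), with Mnx1 at -3.33 ± 0.83, mitochondrially encoded genes in 2 of 10 (0) and nuclear-encoded respiratory chain genes in 5 of 12 (2), with Ndufa4 at -0.79 ± 0.16, at adjusted p = 0.0494, 0.0454 and 0.0124, and adjusted p = 0.456, 0.661 and 0.543 with an estimated correlation. Leaving out 1 library ended the calls for neutrophil markers (adjusted p = 0.0528 and 0.0628 without uninjured replicate 1 and 72 h replicate 1), red blood cell genes (0.0528 and 0.0661 without uninjured replicates 1 and 2), interferon response genes (0.0616 without 72 h replicate 4), respiratory chain genes (0.0603 without 72 h replicate 3), motor neuron genes (0.0552, 0.0579 and 0.0514 without 3 h replicates 1 to 3, 0.0505 without 24 h replicate 3, and 0.106, 0.0809 and 0.0584 without 72 h replicates 1, 3 and 4) and mitochondrially encoded genes (0.129 and 0.121 without uninjured replicates 1 and 4, 0.0504 without 3 h replicate 3, and 0.0503, 0.129 and 0.0583 without 72 h replicates 1, 2 and 4). Calls also ended in white matter spots alone for red blood cell genes (0.347), mural cell markers (0.106), respiratory chain genes (0.326) and motor neuron genes (0.091). They ended in gray matter spots alone for motor neuron genes (0.1) and mitochondrially encoded genes (0.0513), and without the position term for the same lists (0.0685 and 0.0678). Mitochondrially encoded genes also lost the call by fry (0.149), and they and the respiratory chain genes lost it without the 0.5 mm libraries of 72 h (0.129 and 0.146). Lists without a shift at 72 h were heat shock (7 higher and 2 lower of 12), lymphocyte markers (2 and 0 of 3), oligodendrocyte precursor markers (3 and 2 of 10), endothelial and barrier genes (6 and 0 of 14), ependymal markers (2 and 0 of 9), Schwann cell markers (1 and 0 of 7), skeletal muscle genes (1 and 1 of 8) and hypoxia and glycolysis genes (6 and 3 of 13), with adjusted p of 0.0795 to 0.694. Of these, heat shock genes passed in white matter spots alone (0.0181) and by fry (8.4e-04), and lymphocyte markers (0.0052) and endothelial and barrier genes (0.0094) by fry. Among the precursor markers Vcan was at 1.72 ± 0.19 and Cspg4 at 1.74 ± 0.31. Of all list tests at the 3 times 62 passed with the preset correlation, 1 with an estimated correlation and 60 by fry, which tests whether a list moves one way on balance. Median, mean and test differed in sign for pan-neuronal genes, transmitter genes, ependymal markers, Schwann cell markers and antigen presentation genes at 3 h, mural cell markers and complement genes at 24 h, and oligodendrocyte precursor markers, ependymal markers and skeletal muscle genes at 72 h. Libraries share animals, so p-values are too small.

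A cluster of 37 spots, at least 20 of them in 1 library, was led by Pirt, Fxyd2, Avil, Scn11a and Scn10a, genes of sensory neurons of dorsal root ganglia. Pirt reached 46.0 CPM in 3 h replicate 1 and 51.5 CPM in 72 h replicate 2 and stayed under 1.30 CPM in the other libraries.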
